A study of Mus musculus with 11 samples.

How the data were processed

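Gene expression was measured on 11 Affymetrix MG_U74Av2 arrays, a mouse GeneChip with 12488 probe sets, each hybridised with RNA of 1 culture. The groups were read from the sample titles. There were 3 arrays of undifferentiated R1 embryonic stem (ES) cells (replicates 1, 5 and 9), 3 of cells differentiated for 4+8 days (replicates 1, 2 and 3), 3 of cells differentiated for 4+11 days (replicates 4, 8 and 12) and 2 of fibroblast feeder cells (replicates 6 and 10). Per the labels, the cultures were grown as independent triplicates, so p-values for these groups rest on separate cultures. Feeder replicate 10 has the ES cell line as source name and feeder layer as title. The title was used, and the array correlated at 0.969 with feeder replicate 6. The labels do not say whether the 2 feeder arrays came from separate cultures, so p-values that involve them may measure only technical spread. There were 0 identical columns.

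The deposited values were probe set intensities on a linear scale, from 0 upwards. The chip type comes from the experiment files, and the software that summarised the probes is not given in the sources used here. From the values, the 3 arrays of the 4+8 day group had been scaled by the authors to a common trimmed mean of 200.1, while the other 8 arrays had trimmed means of 86.15 to 160.2 (2% trimmed at each end) and no common target. The highest trimmed mean was 2.32 times the lowest, above the ratio of 1.25 set for use of the table as deposited. The intensities were therefore quantile normalised over all 11 arrays. Detection calls were not used.

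Values were tested as log2(intensity + 8), where 8 is the 20th percentile of all values, so a fold change is on that scale and understates the change of dim genes. The 66 control probe sets were left out of the tests. Probe sets above 33.4, the 40th percentile of the normalised values, on at least 2 arrays were kept, which left 8940. Among the 12422 probe sets that are not controls, 10833 had 1 gene symbol in the platform annotation, 396 had several and 1193 were unnamed here. No gene was named from a probe set with several symbols. A gene with several probe sets was represented by the one with the highest mean over all arrays, which gave 6650 genes.

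Each comparison was fitted with limma 3.58.1 in R 4.3.3, using lmFit and eBayes on all 11 arrays with the 4 groups as the only factor. The residual degrees of freedom were 7 and the prior degrees of freedom 3. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the probe sets tested, and a call is an adjusted p below 0.05. All groups shared 1 estimate of the spread. Every adjusted p for a single gene is from this fit unless another is named. Gene intensities are given as the mean ± SD of the quantile-normalised values, and log2 differences with their SE.

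The 5 comparisons, the tests, 14 gene lists, the rule for named genes and most processing alternatives were set before the data were examined. Lists held genes of pluripotency, neural progenitors, neurons, dopaminergic neurons, glia, mesoderm and muscle, endoderm, fibroblasts and their matrix, blood and endothelium, the cell cycle, imprinted genes, Hox genes, stress and immediate early genes, and sex-linked genes. Lists with at least 5 measured members were tested against all other genes with camera (limma, preset correlation of 0.01), adjusted over 65 list tests, and again with a correlation estimated from the data (statmod 1.5.0). The sex-linked list had 2 measured members and no test. Named genes were, per comparison, the 8 with the largest rise and the 8 with the largest fall among called genes whose groups did not overlap, up to 3 called members of each list with the largest change, and a fixed set of markers (Nes, Pou5f1, Nanog, Sox2, Zfp42, Fgf4, Sox1, Pax6, Tubb3, Th, Nr4a2, Gfap, Afp, Gata4, Col1a1, Col3a1, Xist, Cdk1 and Mki67). Map2 and Vim, also in that set, had no tested probe set with 1 symbol. Other list members stand beside a list's count as examples and were chosen after their values were seen.

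The experiment files gave a scan session and a chip lot for all arrays, and a fluidics run (washing and staining) for all but the 4+8 day arrays. The 4+8 day arrays had their own scan session and chip lot, so in both comparisons involving them group and session cannot be told apart. The other 8 arrays shared 1 session and 1 lot and lay in 3 fluidics runs. Run 1 held undifferentiated replicates 1 and 5, 4+11 day replicate 4 and feeder replicate 6. Run 2 held undifferentiated replicate 9, 4+11 day replicate 8 and feeder replicate 10, and run 3 held 4+11 day replicate 12. Of these 8, undifferentiated replicate 9 and 4+11 day replicate 12 were washed under another protocol, each with its own settings. For the 3 comparisons among these 8 arrays, values with the run as a block and within runs 1 and 2 are given beside the pooled ones. Run 3 held 1 array, so the run term takes up 4+11 day replicate 12, which then adds nothing to the block values.

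The code was tested on simulated data in which 100 of 8940 probe sets changed at each size. At a log2 change of 1, it recovered 28% of them for 4+8 days against undifferentiated, 32% for 4+11 days against undifferentiated, 27% between the differentiated groups, 29% for feeder against undifferentiated and 24% for 4+11 days against feeder. At a log2 change of 2 the shares were 75%, 81%, 68%, 67% and 68%. False calls made up 3.74%, 4.24%, 8.65%, 5.88% and 8% of calls, which is above the nominal 5% in the last 3 comparisons.

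The alternatives were values as deposited, median scaling, pseudocounts at the 5th and 40th percentiles, no filter and a filter at the 60th percentile, a trended and robust prior, only the arrays of the 2 groups, a threshold of 1 on the absolute log2 change, the fluidics run as a block, the median over a gene's probe sets, and each array left out in turn. Fits without the 4+8 day arrays, fits without the 2 arrays of the other wash protocol, list tests without each array and the correlation between runs were added after seeing the data. With 1 feeder array left, its spread was taken from the other groups.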

Results

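The data describe how RNA levels of ES cell line R1 changed on differentiation into cells expressing nestin, an intermediate filament protein of neural progenitors. Undifferentiated cells and cells after 4+11 days were also compared with the embryonic fibroblasts on which ES cells are grown. Undifferentiated cells (n = 3), cells after 4+8 days (n = 3) and 4+11 days (n = 3) of differentiation and feeder cells (n = 2) were profiled on 1 array each. Of 8940 probe sets tested, the first principal component (35.1% of the variance) parted undifferentiated cells, at 45.2 to 53.3, from 4+8 day cells, at −55.5 to −45.0. The second (24.5%) placed the feeder arrays highest, at 41.2 and 42.2. Replicates correlated at 0.957 to 0.967 (Spearman, across probe sets, which are not independent) in undifferentiated cells, 0.882 to 0.958 at 4+11 days, 0.810 to 0.884 at 4+8 days and 0.969 between the feeder arrays. The median SD of log2 intensity was 0.45 at 4+8 days against 0.20 in undifferentiated cells, 0.26 at 4+11 days and 0.16 in feeder cells.

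**Figure D1:**
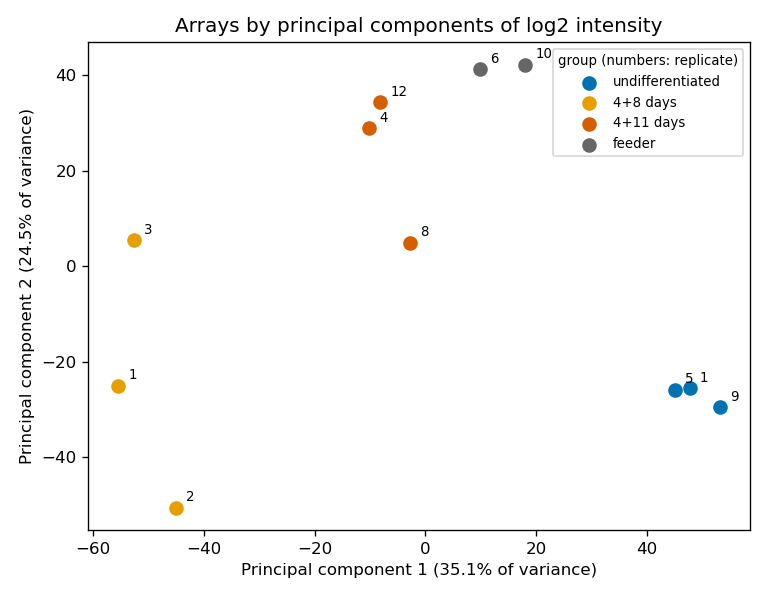
Each point is 1 array, numbered by replicate and coloured by group, placed by principal component 1 (35.1% of the variance) on the horizontal axis and component 2 (24.5%) on the vertical axis. The undifferentiated arrays lie at 45.2 to 53.3 on component 1.

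The beta-actin 3' to 5' ratio, a sign of RNA integrity, was 1.94 ± 0.241 (SD, n = 3) at 4+8 days, 1.71 ± 0.191 (n = 3) in undifferentiated cells, 1.63 ± 0.187 (n = 3) at 4+11 days and 1.55 ± 0.112 (n = 2) in feeder cells. Two-sided exact permutation tests gave p = 0.2 for 4+8 days against undifferentiated, 0.5 for 4+11 days against undifferentiated and 0.2 between the differentiated groups. The Gapdh ratio was 0.935 at 4+8 days, 0.997 in undifferentiated cells and 1.01 at 4+11 days, with exact p = 0.2, 0.9 and 0.2 for the same pairs. The smallest p for 3 against 3 arrays is 0.1.

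The first comparison asked how cells after 4+8 days differed from undifferentiated ES cells. Among the largest rises were genes of the heart's contractile apparatus. Myh7, a cardiac myosin heavy chain read by a probe set that may also bind related myosins, had a mean intensity of 2953 ± 1397 (SD, n = 3) at 4+8 days and 13.1 ± 2.14 (n = 3) in undifferentiated cells, a log2 difference of 7.02 ± 0.62 (SE, adjusted p = 6.77e-05). The atrial myosin light chains Myl7 and Myl4 rose by 6.11 ± 0.60 and 5.27 ± 0.49, and troponin genes Tnnc1 and Tnnt2 by 5.11 ± 0.55 and 4.75 ± 0.48. Regulators of pluripotency were among the largest falls: Pou5f1, which encodes Oct4, went from 2166 ± 538.5 (n = 3) to 28.0 ± 4.63 (n = 3), a log2 difference of −5.90 ± 0.24 (adjusted p = 1.04e-06). Zfp42 (Rex1) changed by −6.90 ± 0.18 and Dppa5a by −7.34 ± 0.57, and Nanog, which sustains self-renewal, by −5.29 ± 0.23 (adjusted p = 1.58e-06).

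Of 33 measured pluripotency genes, 30 fell, 0 rose and 3 did not pass (31 fell when adjusted over the list alone, or "within the list"; camera adjusted p = 9.84e-19, and adjusted p = 0.00367 with an estimated correlation). Sox2, a factor shared by ES cells and neural progenitors, was among them at −3.32 ± 1.02 (adjusted p = 0.0288), with intensities of 430.5, 1342 and 74.3 in 4+8 day replicates 1, 2 and 3. Its call was lost without 4+8 day replicate 1 (adjusted p = 0.0552) or 3 (0.0817) and without undifferentiated replicate 1 (0.0737), 5 (0.0626) or 9 (0.0771), or without the other wash protocol (0.0629). Of 44 cell cycle genes 24 fell, 0 rose and 20 did not pass (26 fell within the list), among them Pola1, a DNA polymerase subunit (−1.87 ± 0.28), Bub1 of the spindle checkpoint (−1.76 ± 0.38) and Cdc6, a replication licensing factor (−1.55 ± 0.32). The list had a camera adjusted p of 2.06e-06, and an adjusted p = 0.647 with an estimated correlation. The count of falls was 13 without undifferentiated replicate 1 and 14 without replicate 9, and 0 with values as deposited.

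Mesoderm and muscle genes rose in 14 of 26 measured cases, 1 fell and 11 did not pass (14 and 1 within the list; camera adjusted p = 7.55e-05, adjusted p = 0.469 with an estimated correlation). Hand2, a factor of the developing heart, was at 2.69, and Tcf15 was the member that fell, at −3.12. In the endoderm list 12 of 27 genes rose, 1 fell and 14 did not pass (14 and 1 within the list), among them Gata6, an endoderm and heart transcription factor (3.66 ± 0.45, adjusted p = 0.000347), and Foxa1 (2.34 ± 0.52). Its camera adjusted p was 0.000153, and the adjusted p = 0.350 with an estimated correlation, and 7 members rose without undifferentiated replicate 1. Of 22 imprinted genes 13 rose, 1 fell and 8 did not pass (14 and 1 within the list; camera adjusted p = 6.04e-05, adjusted p = 0.350 with an estimated correlation). Plagl1 rose by 4.70 ± 0.53, and Dlk1, a Notch pathway ligand, went from 262.5 ± 48.3 to 4308 ± 2333 (n = 3 each), a log2 difference of 3.83 ± 0.46 (adjusted p = 0.000314). In the blood and endothelium list 8 of 27 rose, 0 fell and 19 did not pass (8 within the list; 10 rose and 1 fell at an unadjusted p below 0.05). They included Cdh5, the endothelial cadherin (3.21 ± 0.29, adjusted p = 6.84e-05), and embryonic and adult globins such as Hbb-bh1 (2.58 ± 0.56) and Hba-a1 (2.98 ± 0.59), whose probe sets may bind each other's transcripts. The camera adjusted p was 0.00492, and the adjusted p = 0.735 with an estimated correlation, and 17 members rose without 4+8 day replicate 2.

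No neural list was called. Of 31 neural progenitor genes 5 rose, 2 fell and 24 did not pass (4 and 2 within the list; camera adjusted p = 0.0768, and 0.835 with an estimated correlation). Mdk, a growth factor, rose by 1.67 ± 0.37 and Gbx2, a patterning factor, changed by −2.83 ± 0.35. Nes itself was at 281.3 ± 118.8 against 192.3 ± 25.9 (n = 3 each), a log2 difference of 0.46 ± 0.32 (adjusted p = 0.270; 1.28 and 0.00868 with values as deposited). Of 35 neuron genes 4 rose, 3 fell and 28 did not pass (3 and 2 within the list; camera adjusted p = 0.283, and 0.917 with an estimated correlation). Ncam1, a neural cell adhesion molecule, rose by 2.13 ± 0.37, Isl1, a factor of motor neurons and cardiac progenitors, by 2.07 ± 0.26, and the neurofilament gene Nefh changed by −2.05 ± 0.54, a call lost without undifferentiated replicate 9 (adjusted p = 0.0517), without the other wash protocol (0.0724) and with values as deposited (0.150). Without 4+8 day replicate 3 the camera adjusted p was 0.0112 for the neural progenitor list, with 10 members rising, and 0.0271 for the neuron list, with 9 rising. Without 4+8 day replicate 2, undifferentiated replicate 1 or 9, 2 members of each list rose, and without the first of these the neuron list lay below other genes (camera adjusted p = 0.815) with 6 falls. Without undifferentiated replicate 9, 1 neuron gene fell. Of 15 dopaminergic genes 3 rose, 3 fell and 9 did not pass (3 and 3 within the list; camera adjusted p = 0.519, and 0.772 with an estimated correlation). Th, the rate-limiting enzyme of dopamine synthesis, went from 25.9 ± 12.5 to 102.8 ± 28.6 (n = 3 each), a log2 difference of 1.75 ± 0.35 (adjusted p = 0.00407), while Wnt5a changed by −2.09 ± 0.27. Of 16 glia genes 3 rose, 1 fell and 12 did not pass (3 and 1 within the list; camera adjusted p = 0.259, and 0.647 with an estimated correlation), with the myelin genes Pmp22 (2.83 ± 0.31) and Mbp (1.27 ± 0.23) among the rises, and 5 rises without 4+8 day replicate 2.

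Fibroblast and matrix genes divided: 11 of 48 rose, 10 fell and 27 did not pass (13 and 13 within the list; camera adjusted p = 0.651, and 0.934 with an estimated correlation). Col3a1 rose by 1.61 ± 0.31, while the stromelysin Mmp3 (−6.46 ± 0.49), the chemokine Cxcl1 (−5.45 ± 0.87) and Thy1 (−5.13 ± 0.54) fell. Without 4+8 day replicate 2, 17 rose and the list lay above other genes (camera adjusted p = 0.588), and without undifferentiated replicate 9, 5 rose; with values as deposited its median was 0.93 in place of −0.08 and the camera adjusted p 0.0198. Of 22 Hox genes 4 rose, 2 fell and 16 did not pass (4 and 1 within the list; camera adjusted p = 0.255, and 0.740 with an estimated correlation), among them Hoxb13 at 1.70 ± 0.39 and Hoxa11 at −1.23 ± 0.27. With values as deposited the Hox list passed (0.0281) and the Hoxa11 call was lost (−0.15, adjusted p = 0.695). Of 36 stress and immediate early genes 2 rose, 9 fell and 25 did not pass (2 and 9 within the list; camera adjusted p = 0.131, and 0.812 with an estimated correlation). Hsph1, a chaperone gene, was at −2.04 ± 0.28. Without undifferentiated replicate 1 or 4+8 day replicate 3 the camera adjusted p was 0.00566 or 0.0445, and with values as deposited 0.000748 beside a median of 0.20 in place of −0.58. The falls numbered 5 without 4+8 day replicate 1, undifferentiated replicate 5 or 9. Xist, the RNA of the inactive X chromosome, changed by −1.42 ± 0.37 (adjusted p = 0.0138), and with values as deposited its adjusted p was 0.556.

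In this comparison 3316 probe sets (37.1%) passed, 1538 higher and 1778 lower, or 1170 and 1338 genes. Group values did not overlap in 48.2% of probe sets, against 10% by chance. With values as deposited (median of all probe sets 1.07 log2) 6052 passed, 5665 of them higher, a share of 93.6% against 46.4% after quantile normalisation. Group and scan session cannot be told apart. Calls held in every leave-one-out fit for 46 of 52 named genes.

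**Figure D2:**
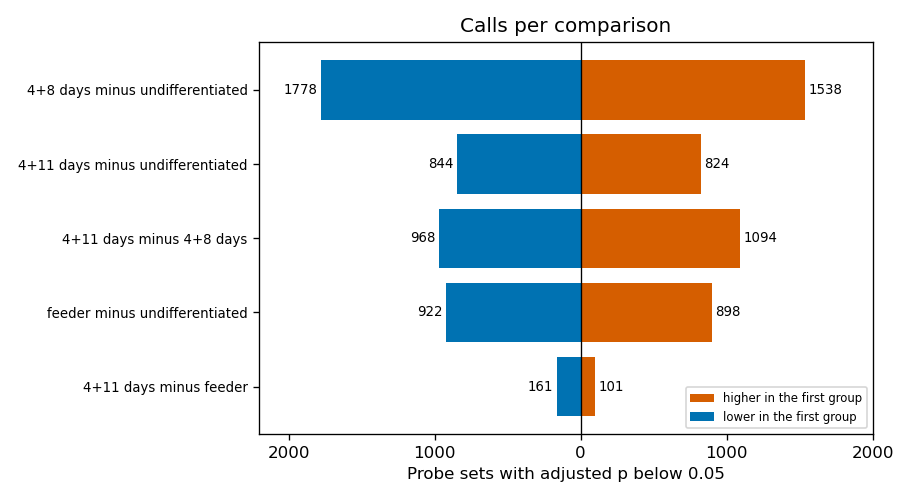
Bars give the number of probe sets with an adjusted p below 0.05 in each comparison, to the right where the first group named was higher and to the left where it was lower. The counts run from 1538 higher and 1778 lower for 4+8 days against undifferentiated to 101 higher and 161 lower for 4+11 days against feeder.

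The second comparison asked the same of cells after 4+11 days. Pluripotency genes were again among the largest falls: Pou5f1 was at 9.76 ± 3.12 (SD, n = 3) against 2166 ± 538.5 (n = 3) in undifferentiated cells, a log2 difference of −6.92 ± 0.24 (SE, adjusted p = 2.14e-07), and Nanog changed by −5.89 ± 0.23 and Utf1 by −5.96 ± 0.24. Fgf4, an autocrine growth factor of ES cells, changed by −3.16 ± 0.26. Among the largest rises were Plagl1 (4.71 ± 0.53, adjusted p = 0.000575), the hematopoietic transcription factor Lyl1 (4.48 ± 0.88; adjusted p = 0.0799 without the other wash protocol), the ventricular myosin light chain Myl2 (4.39 ± 0.65) and the cardiac stress gene Ankrd1 (4.18 ± 0.60). Nes was at 460.3 ± 120.4 against 192.3 ± 25.9 (n = 3 each), a log2 difference of 1.20 ± 0.32 (adjusted p = 0.0260), higher in all 3 arrays. Its call was lost without undifferentiated replicate 1 (adjusted p = 0.0603), 5 (0.0689) or 9 (0.0968), without 4+11 day replicate 4 (0.0643) or 8 (0.0732) without the other wash protocol (0.138) and with the fluidics run as a block (log2 1.34, adjusted p = 0.0669).

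Of 33 pluripotency genes 28 fell, 0 rose and 5 did not pass (32 fell within the list; camera adjusted p = 4.64e-29, and 0.00180 with an estimated correlation). Their median log2 difference was −3.70, −3.62 with the run as a block, and −3.47 and −3.81 within runs 1 and 2. Sox2 did not pass (−2.80 ± 1.02, adjusted p = 0.0857), with intensities of 424.7, 2106 and 151.0 in replicates 4, 8 and 12, and passed without replicate 8 (−3.82, adjusted p = 0.0243) or the 4+8 day arrays (0.0318). Of 44 cell cycle genes 20 fell, 0 rose and 24 did not pass (28 fell within the list; camera adjusted p = 5.19e-10, adjusted p = 0.516 with an estimated correlation), among them the helicase gene Mcm5 (−1.64 ± 0.28) and Cdc6 (−1.57 ± 0.32), both lost without the other wash protocol (adjusted p = 0.0602 and 0.101). The median was −0.87, −0.73 with the block, and −0.89 and −0.50 within runs. There were 9 falls with the block, 4 with values as deposited, 7 without undifferentiated replicate 1 or 9 or 4+11 day replicate 4 or 12, and 11 without undifferentiated replicate 5.

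Mesoderm and muscle genes rose in 12 of 26 cases, 1 fell and 13 did not pass (12 and 1 within the list; camera adjusted p = 0.00172, adjusted p = 0.516 with an estimated correlation). Myh7 was at 3.88 ± 0.62 and Tnnc1 at 3.41 ± 0.55 (adjusted p = 0.0552 without the other wash protocol). The median was 0.73, 0.62 with the block, and 1.01 and 0.12 within runs. Imprinted genes rose in 12 of 22 cases, 2 fell and 8 did not pass (13 and 2 within the list; camera adjusted p = 0.000156, adjusted p = 0.377 with an estimated correlation). Peg3 was at 2.68 ± 0.33, and Phlda2 changed by −3.82 ± 0.34. Their median was 1.42, 1.38 with the block, and 1.37 and 1.57 within runs. In the endoderm list 5 of 27 rose, 2 fell and 20 did not pass (9 and 2 within the list; camera adjusted p = 0.00644, adjusted p = 0.516 with an estimated correlation), among them Gata6 (3.35 ± 0.45) and Foxa1 (2.83 ± 0.52). The median was 0.73, 0.47 with the block, and 0.88 and 0.08 within runs, 9 rose without 4+11 day replicate 8, and with values as deposited the list's adjusted p was 0.135.

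In the blood and endothelium list 7 of 27 rose, 0 fell and 20 did not pass (11 within the list; 12 rose and 2 fell at an unadjusted p below 0.05; camera adjusted p = 0.0122, adjusted p = 0.746 with an estimated correlation). The largest rises were the macrophage genes C1qb (4.84 ± 1.37, adjusted p = 0.0358), Tyrobp (4.43 ± 1.29, adjusted p = 0.0393) and Ctss (4.06 ± 1.12, adjusted p = 0.0320), followed by Cdh5 (2.89). Tyrobp was at 877.5, 126.0 and 1396 in replicates 4, 8 and 12, and all 3 of these calls were lost without undifferentiated replicate 1, 5 or 9 or 4+11 day replicate 4 or 12 (adjusted p up to 0.119 for C1qb, 0.129 for Tyrobp and 0.117 for Ctss). They were also lost with the fluidics run as a block (C1qb 4.35, adjusted p = 0.107; Tyrobp 3.97, 0.127; Ctss 3.68, 0.0660) and without the other wash protocol (0.271, 0.274 and 0.268), and Tyrobp without a filter (0.0509). The list's median was 0.96, 1.02 with the block, and 1.06 and 0.40 within runs. With the block 3 rose, as without undifferentiated replicate 5 or 9 or 4+11 day replicate 4 or 12; 4 rose without undifferentiated replicate 1 and 12 without 4+11 day replicate 8. Without the other wash protocol the list's adjusted p was 0.0713.

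Of 31 neural progenitor genes 7 rose, 1 fell and 23 did not pass (8 and 1 within the list; camera adjusted p = 0.020, adjusted p = 0.780 with an estimated correlation). Beside Nes these were Sox11, a factor of immature neurons (2.30 ± 0.71, adjusted p = 0.0492), the growth factor Ptn (1.89 ± 0.46, adjusted p = 0.0196), Sox4 (1.62) and the Meis factors, while Gbx2 changed by −2.09 ± 0.35. The median was 0.56, 0.83 with the block (camera adjusted p = 0.000459), and 0.34 and 1.77 within runs. Both lack replicate 12, the group's lowest. Without 4+11 day replicate 8 the list's adjusted p was 0.474, and with values as deposited 0.105. There were 4 rises with the block, 1 without undifferentiated replicate 1 or 9 or 4+11 day replicate 4 or 8, and 2 without undifferentiated replicate 5. The call of Sox11 was lost without undifferentiated replicate 1, 5 or 9 or 4+11 day replicate 4 or 8 (adjusted p up to 0.131), without the other wash protocol (0.0641), without a filter (0.0640) and with the 5th percentile pseudocount (0.0565), and that of Ptn without undifferentiated replicate 1 or 9 or 4+11 day replicate 4 or 8 (up to 0.0801). Of 35 neuron genes 3 rose, 1 fell and 31 did not pass (1 and 1 within the list; camera adjusted p = 0.180, and 0.917 with an estimated correlation). Ncam1 was at 1.80 ± 0.37. The median was 0.42, 0.74 with the block (camera adjusted p = 0.00941), and 0.50 and 1.17 within runs. Without 4+11 day replicate 12 the adjusted p was 0.00443 and 5 rose. Without replicate 8 the list lay below other genes (adjusted p = 0.886), and 1 member rose, as without each undifferentiated replicate in turn.

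The remaining lists had no call. Of 16 glia genes 3 rose, 0 fell and 13 did not pass (3 within the list; 4 rose and 1 fell at an unadjusted p below 0.05; camera adjusted p = 0.291, and 0.703 with an estimated correlation), namely Clu (2.11 ± 0.40; adjusted p = 0.0779 without the other wash protocol), Pmp22 (1.95 ± 0.31) and Mbp (1.56 ± 0.23). The glia median was 0.16, 0.04 with the block, and −0.02 and 0.72 within runs, and it was 0.00 without 4+11 day replicate 8. In the dopaminergic list 1 of 15 fell, Pitx3 (−0.69 ± 0.21, adjusted p = 0.0489), and 0 rose (0 and 0 within the list; 1 fell and 0 rose at an unadjusted p below 0.05). The camera adjusted p was 0.878 (0.934 with an estimated correlation), with a test direction down beside a median of 0.14 (0.01 with the block, −0.04 and 0.26 within runs). That median was −0.16 without undifferentiated replicate 1, −0.14 without replicate 9, −0.11 without 4+11 day replicate 8 and −0.06 without replicate 12, where the test direction was up (0.740). The Pitx3 call was lost without undifferentiated replicate 1 or 5 or any 4+11 day array (adjusted p up to 0.174) and with the run as a block (−0.60, adjusted p = 0.190). Values as deposited (0.221), the 40th percentile pseudocount (0.130), no filter (0.0692), the trended prior (0.132), only the 2 groups (0.0549) and leaving out the other wash protocol (0.0980) also ended it. Fibroblast and matrix genes rose in 9 of 48 cases, 5 fell and 34 did not pass (10 and 6 within the list; camera adjusted p = 0.651, and 0.934 with an estimated correlation). Tgfbi rose by 2.87 ± 0.34 and Mmp3 changed by −6.23 ± 0.49, and the list's median of 0.03, mean of −0.06 and upward test differed in sign. The median was 0.00 with the block and 0.24 and 0.11 within runs. It was −0.11 and −0.03 without 4+11 day replicates 4 and 12, and the test direction was down with values as deposited (0.741). Of 22 Hox genes 1 fell, Hoxd10 (−1.30 ± 0.26), and 0 rose (1 fell within the list; 3 fell and 0 rose at an unadjusted p below 0.05; camera adjusted p = 0.337, and 0.772 with an estimated correlation), with a median of −0.17 (−0.19 with the block, −0.11 and −0.05 within runs) that was 0.04 with values as deposited. Of 36 stress and immediate early genes 1 rose, 4 fell and 31 did not pass (0 and 1 within the list; camera adjusted p = 0.0705, and 0.780 with an estimated correlation). Pdk1, a metabolic kinase gene, was at −1.90 ± 0.24. Its median was −0.58, −0.76 with the block, and −0.26 and −0.87 within runs. The camera adjusted p was 0.0298 with the block, 0.0180 with values as deposited, 0.000758 without undifferentiated replicate 1, and 0.0263 and 0.0313 without 4+11 day replicates 4 and 12. Its falls numbered 2 with the block or without 4+11 day replicate 8 or 12, and 1 without 4+11 day replicate 4 or undifferentiated replicate 5 or 9. Xist changed by −1.83 ± 0.37 (adjusted p = 0.00861; 0.0646 without the other wash protocol).

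Between 4+11 days and undifferentiated cells 1668 probe sets (18.7%) passed, 824 higher and 844 lower, or 664 and 668 genes, and groups did not overlap in 46.3% against 10% by chance. With values as deposited (median of all probe sets 0.26 log2) 82.5% of calls were higher against 49.4%. With the fluidics run as a block 899 passed, 853 of them shared, and across all probe sets the log2 differences within runs 1 and 2, which share no array, correlated at 0.719 (Pearson). The count was 873, 1006 and 825 without undifferentiated replicates 1, 5 and 9, and 775 and 1078 without 4+11 day replicates 4 and 12. It was 395 without the other wash protocol. Calls held in every leave-one-out fit for 34 of 46 named genes.

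**Figure D3:**
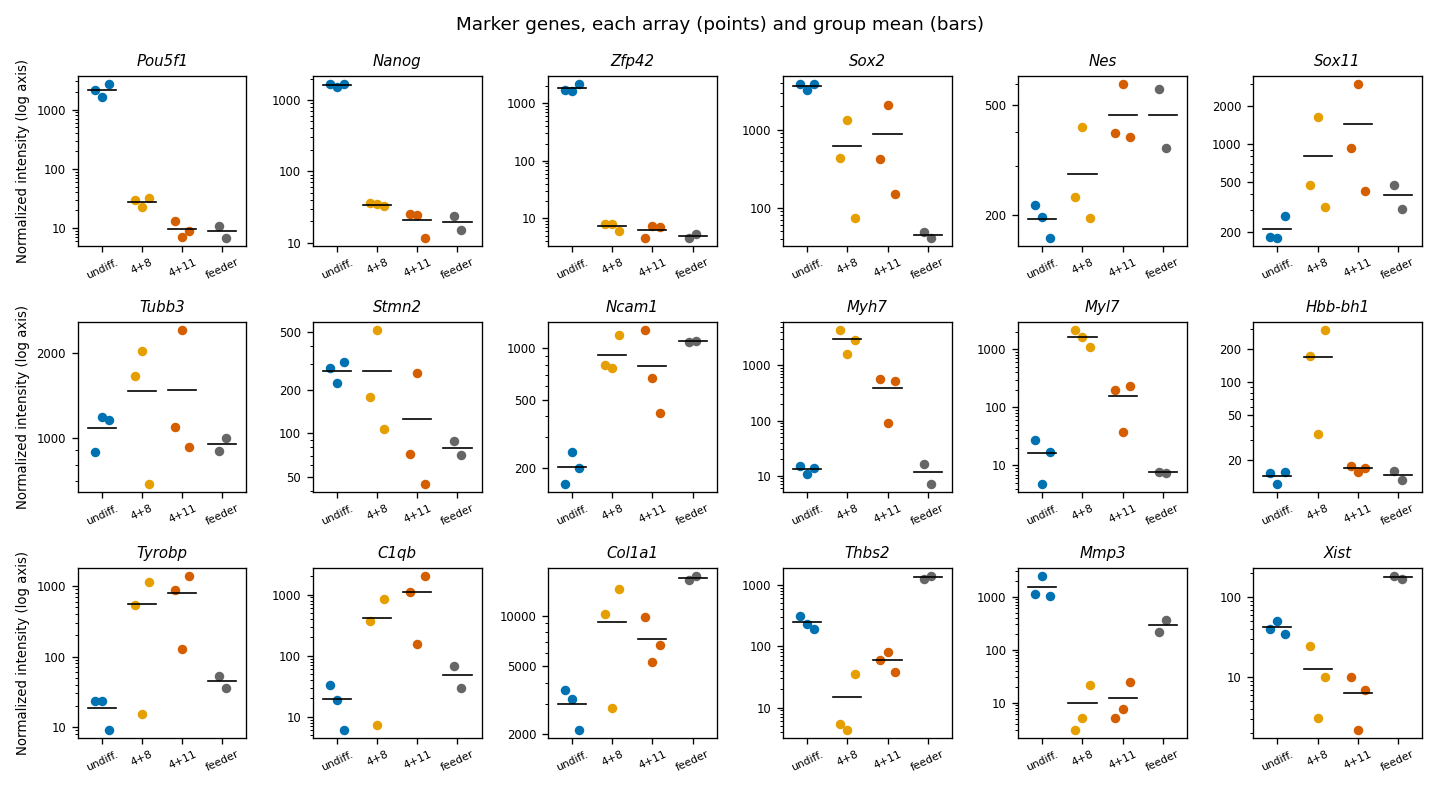
Each panel gives 1 marker gene, with the normalised intensity of each array as points on a log axis and the group mean as a bar, for undifferentiated, 4+8 day, 4+11 day and feeder samples. Nes had a mean of 192.3 in undifferentiated and 460.3 in 4+11 day cells, and Sox2 ranged from 151.0 to 2106 among the 4+11 day arrays.

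The third comparison asked what differed between the differentiation times. Among the largest falls was that of Myl7, which was at 155.9 ± 104.2 (SD, n = 3) after 4+11 days and 1607 ± 541.5 (n = 3) after 4+8 days, a log2 difference of −3.57 ± 0.60 (SE, adjusted p = 0.00447), and Myh7 changed by −3.14 ± 0.62 and Myl4 by −2.82 ± 0.49. Thy1, at 270.0 ± 193.0 against 15.5 ± 14.1 (n = 3 each), rose by 3.48 ± 0.54 (adjusted p = 0.00354), Emp1 by 3.51 ± 0.40 and the cell cycle inhibitor Cdkn2b by 2.94 ± 0.44. The calls of Arg1 (3.04 ± 0.81) and the prostaglandin synthase Ptgs2 (3.04 ± 0.83), also among the largest rises, were lost without 4+8 day replicate 2 or 4+11 day replicate 4 or 12 and for Ptgs2 also without 4+8 day replicate 1 (adjusted p up to 0.0830 and 0.0783), and without the other wash protocol (0.0580 and 0.104). Nes did not pass (0.74 ± 0.32, adjusted p = 0.117) and passed without 4+8 day replicate 2 (1.07, adjusted p = 0.0237) and with median scaling (1.01, 0.0261).

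Of 26 mesoderm and muscle genes 10 fell, 1 rose and 15 did not pass (10 and 1 within the list; camera adjusted p = 0.00209, adjusted p = 0.516 with an estimated correlation), and 6 fell without 4+11 day replicate 8. Of 22 Hox genes 5 fell, 1 rose and 16 did not pass (6 and 1 within the list; camera adjusted p = 0.00814, adjusted p = 0.393 with an estimated correlation). Hoxb1 was at −1.42 ± 0.31 and Hoxa4 at −1.41 ± 0.22. The falls numbered 2 without 4+8 day replicate 1 or 4+11 day replicate 4, 12 with median scaling and 18 with values as deposited. In the dopaminergic list 2 of 15 rose, Wnt5a (2.66 ± 0.27) and En1 (2.28 ± 0.43), and 3 fell, with 10 that did not pass (2 and 3 within the list; camera adjusted p = 0.289, and 0.647 with an estimated correlation). The falls included Pitx3, a midbrain dopaminergic factor (−1.91 ± 0.21, adjusted p = 0.000914), and Th, at 29.3 ± 9.72 against 102.8 ± 28.6 (n = 3 each), a log2 difference of −1.57 ± 0.35 (adjusted p = 0.0129; 0.0551 without 4+11 day replicate 4). Of 33 pluripotency genes 3 fell, 0 rose and 30 did not pass (3 within the list; 6 fell and 1 rose at an unadjusted p below 0.05; camera adjusted p = 0.0768, and 0.516 with an estimated correlation), Pou5f1 (−1.02 ± 0.24, adjusted p = 0.0142; 0.0627 with the 40th percentile pseudocount) and Fgf4 (−1.59 ± 0.26) among them. The list's adjusted p was 0.0252 without 4+8 day replicate 3, with 7 falls, 0.0384 and 0.0464 without undifferentiated replicates 1 and 9, and 0.0301 with values as deposited.

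Blood and endothelium genes fell in 7 of 27 cases, 1 rose and 19 did not pass (7 and 1 within the list; camera adjusted p = 0.330, and 0.917 with an estimated correlation). Hba-a1 (−2.50 ± 0.59) and Hbb-bh1 (−2.43 ± 0.56) were among the falls and Runx1, a factor of blood formation, rose (2.41). The median of 0.12 differed in sign from the mean and test, and was −0.32 without 4+8 day replicate 2 (camera adjusted p = 0.0141), −0.07 without 4+11 day replicate 4, when 4 fell, and −0.07 without replicate 12. Without 4+11 day replicate 8 the test direction was up (0.886), and with values as deposited the median was −0.63. Fibroblast and matrix genes rose in 11 of 48 cases, 2 fell and 35 did not pass (11 and 2 within the list; camera adjusted p = 0.135, and 0.868 with an estimated correlation). Cd44, a hyaluronan receptor, was at 1.67. Rises numbered 3 and 6 without 4+8 day replicates 1 and 2, and 2 and 6 without 4+11 day replicates 4 and 12. The camera adjusted p was 0.00589 without 4+8 day replicate 3 and 0.0463 without 4+11 day replicate 8, and the median of 0.39 was −0.07 with values as deposited (camera adjusted p = 0.00534). Of 27 endoderm genes 4 fell, 1 rose and 22 did not pass (3 and 1 within the list; camera adjusted p = 0.0636, and 0.647 with an estimated correlation). Sox17 was at −1.76 ± 0.35 and the protease Plat at 2.25 ± 0.28. The list's adjusted p was 0.0153 without 4+8 day replicate 2, when 8 fell, and 0.0156 and 0.0280 without 4+11 day replicates 4 and 12, when 2 fell, as without 4+8 day replicate 1 or 4+11 day replicate 8.

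No other list was called. Of 22 imprinted genes 3 fell, 1 rose and 18 did not pass (3 and 0 within the list; camera adjusted p = 0.180, and 0.772 with an estimated correlation), Phlda2 at −2.83 ± 0.34. Of 31 neural progenitor genes 2 rose, 2 fell and 27 did not pass (1 and 1 within the list; camera adjusted p = 0.921, and 0.982 with an estimated correlation). Notch1 was at 1.15 and Sox3 at −1.66 ± 0.39 (adjusted p = 0.0154; 0.0567 without 4+11 day replicate 4). Its median of 0.03 was −0.15 without 4+8 day replicate 3, −0.42 without 4+11 day replicate 8, −0.66 with values as deposited and −0.09 with median scaling. The test direction was down without those replicates (0.461 and 0.261) and without 4+8 day replicate 1 (0.805). Of 35 neuron genes 1 rose, 2 fell and 32 did not pass (0 and 1 within the list; camera adjusted p = 0.858, and 0.978 with an estimated correlation). Isl1 was at −1.31 ± 0.26. The neuron median of −0.06 differed in sign from the mean of 0.04, and was 0.36 without 4+8 day replicate 2, 0.14 without 4+11 day replicate 4 and 0.44 without replicate 12, where the test direction was up (0.296, 0.937 and 0.223). Of 16 glia genes 2 fell, 0 rose and 14 did not pass (2 within the list; 3 fell and 2 rose at an unadjusted p below 0.05; camera adjusted p = 0.730, and 0.917 with an estimated correlation). Aldoc, a glycolytic gene, was at −2.39 ± 0.48. The glia median of 0.10 differed in sign from the mean and test, and was −0.07 without 4+11 day replicate 12 and −0.67 with values as deposited. Cell cycle genes changed in 3 of 44 cases, 1 up and 2 down (0 and 0 within the list; camera adjusted p = 0.651, and 0.938 with an estimated correlation). Their median of −0.03, beside a mean of 0.01, was 0.11 with median scaling, 0.11 without 4+8 day replicate 1, 0.04 without 4+11 day replicate 4 and 0.22 without replicate 12. Their camera adjusted p was 0.0330 without replicate 8, and the test direction was up without 4+8 day replicate 1 (0.921) or 4+11 day replicate 12 (0.443). Of 36 stress and immediate early genes 3 rose, 3 fell and 30 did not pass (3 and 2 within the list; camera adjusted p = 0.950, and 0.982 with an estimated correlation). Ddit4 was at 1.49 ± 0.31. That list's median of −0.10 differed in sign from the mean of 0.06, and was 0.15 with median scaling, 0.01 and 0.23 without 4+8 day replicates 1 and 3 and 0.16 without 4+11 day replicate 8. The test direction was down without 4+8 day replicate 1 (0.824) or 2 (0.551) or 4+11 day replicate 4 (0.811) or 12 (0.790). Of these genes 1 rose without 4+8 day replicate 1 or 4+11 day replicate 12 and 5 without 4+8 day replicate 3, while 5 fell without 4+8 day replicate 2, 0 without 4+11 day replicate 8, and 1 without 4+8 day replicate 3 or 4+11 day replicate 4 or 12. Xist did not pass (−0.42 ± 0.37, adjusted p = 0.441; 0.0237 with values as deposited).

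In all 2062 probe sets (23.1%) passed between the differentiation times, 1094 higher and 968 lower after 4+11 days, or 824 and 714 genes, and groups did not overlap in 35.2% against 10% by chance. The count was 969 and 1325 without 4+11 day replicates 4 and 12, and 535 with only the arrays of these groups. With values as deposited (median of all probe sets −0.65 log2) 3733 passed and 5.49% of them were higher, against 53.1%. Group and scan session cannot be told apart here either. With only the arrays of these groups the calls of Myh7, Ptgs2, Hoxb1, Pou5f1, Hba-a1, Hbb-bh1, Sox17, Sox3 and Isl1 were lost (adjusted p from 0.0544 to 0.0814), and without the other wash protocol those of Hoxb1, Th, Hba-a1, Hbb-bh1 and Sox3 (0.0540 to 0.0739). Calls held in every leave-one-out fit for 26 of 48 named genes.

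The fourth comparison set the feeder fibroblasts against undifferentiated ES cells. Among the largest rises in feeder cells was that of the matrix proteoglycan Fmod, at 424.6 ± 86.7 (SD, n = 2) against 9.91 ± 6.13 (n = 3), a log2 difference of 4.63 ± 0.48 (SE, adjusted p = 0.000356), and smooth muscle actin Acta2 was higher by 3.97 ± 0.48, elastin (Eln) by 4.44 ± 0.75 and Col3a1 by 2.30 ± 0.35. Pou5f1 was at 8.91 ± 2.86 (n = 2) in feeder cells, a log2 difference of −6.99 ± 0.26 (adjusted p = 5.87e-07), and Zfp42, Nanog and Dppa5a were at −7.13, −5.93 and −8.77. Sox2 was at 44.7 ± 5.21 (n = 2), a log2 difference of −6.12 ± 1.14 (adjusted p = 0.00604; 0.0522 and 0.0528 without feeder replicates 6 and 10). Nes was higher in feeder cells, at 461.8 ± 156.8 (n = 2) against 192.3 ± 25.9 (n = 3), a log2 difference of 1.20 ± 0.35 (adjusted p = 0.0394). Its call was lost in each leave-one-out fit: 0.0736, 0.0843 and 0.115 without undifferentiated replicates 1, 5 and 9, 0.292 and 0.0696 without feeder replicates 6 and 10, 0.0677 with the run as a block, 0.0533 without a filter and 0.139 without the other wash protocol.

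Of 48 fibroblast and matrix genes 28 rose, 1 fell and 19 did not pass (32 and 1 within the list; camera adjusted p = 7.21e-13, adjusted p = 0.350 with an estimated correlation). The member that was lower in feeder cells was Mmp3 (−2.32). Col1a1 was at 16756 ± 707.3 (n = 2) against 2978 ± 781.6 (n = 3), a log2 difference of 2.53 ± 0.59 (adjusted p = 0.0147), a call lost without feeder replicate 6 (0.0919) or 10 (0.0936) or undifferentiated replicate 9 (0.0556), without the other wash protocol (0.0769) and with median scaling (0.108). The list's median was 1.69, 1.68 with the block, and 1.61 and 1.93 within runs, and 12, 10 and 16 members rose without feeder replicates 6 and 10 and undifferentiated replicate 9. Of 33 pluripotency genes 30 fell and 1 rose, the receptor subunit Il6st (2.21), with 2 that did not pass (30 and 1 within the list; camera adjusted p = 4.75e-26, and 0.00180 with an estimated correlation). Their median was −4.07, −4.07 with the block, and −3.96 and −3.93 within runs. Of 44 cell cycle genes 15 fell, 0 rose and 29 did not pass (16 fell within the list; camera adjusted p = 1.26e-06, adjusted p = 0.647 with an estimated correlation). Mcm5 was at −2.04 ± 0.31. The median was −0.76, −0.79 with the block, and −0.91 and −0.69 within runs. The falls numbered 7, 8 and 7 without undifferentiated replicates 1, 5 and 9 and 2 and 5 without feeder replicates 6 and 10.

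Hox genes, which mark position along the body axis, rose in 7 of 22 cases, 0 fell and 15 did not pass (9 rose within the list; 11 rose and 0 fell at an unadjusted p below 0.05; camera adjusted p = 0.000621, adjusted p = 0.300 with an estimated correlation). Hoxa7 was at 76.8 ± 11.5 (n = 2) against 8.57 ± 0.693 (n = 3), a log2 difference of 2.35 ± 0.20 (adjusted p = 0.000129). The Hox median was 0.81, 0.83 with the block, and 0.59 and 0.69 within runs, and the rises numbered 3 and 4 without undifferentiated replicates 1 and 9 and 1 without either feeder array. Imprinted genes rose in 9 of 22 cases, 1 fell and 12 did not pass (10 and 1 within the list; camera adjusted p = 0.00562, adjusted p = 0.516 with an estimated correlation), Plagl1 at 3.59 ± 0.59 and Phlda2 at −4.35 ± 0.38. Their median was 1.05, 1.14 with the block, and 1.20 and 0.90 within runs, with 4 rises without feeder replicate 6. Of the sex-linked list, Xist was at 180.3 ± 10.3 (n = 2) against 42.4 ± 8.26 (n = 3), a log2 difference of 1.91 ± 0.41 (adjusted p = 0.0110), and Eif2s3y, on the Y chromosome, at 61.0 ± 4.16 against 154.2 ± 29.5 (−1.22 ± 0.24, adjusted p = 0.00728). Both calls were lost without feeder replicate 6 or 10 (adjusted p up to 0.0890 and 0.0686), that of Xist also without the other wash protocol (0.0695) and with the 5th percentile pseudocount (0.0507), and that of Eif2s3y with values as deposited (0.0992).

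The neural and germ layer lists had no call against undifferentiated cells. Neural progenitor genes rose in 3 of 31 cases, 1 fell and 27 did not pass (2 and 1 within the list; camera adjusted p = 0.540, and 0.934 with an estimated correlation). Ptn was at 3.15 ± 0.51. The median was 0.20, 0.16 with the block, and 0.23 and 0.39 within runs, and 1 rose in each leave-one-out fit, without undifferentiated replicate 1, 5 or 9 or feeder replicate 6 or 10. Of 35 neuron genes 3 rose, 3 fell and 29 did not pass (3 and 3 within the list; camera adjusted p = 0.696, and 0.938 with an estimated correlation), Ncam1 at 2.42 ± 0.41. The neuron median of −0.14 (−0.17 with the block, 0.07 and −0.25 within runs) was 0.12 with values as deposited. In the same leave-one-out fits 0 neuron genes fell, and 1 rose without feeder replicate 10. In the dopaminergic list 2 of 15 rose and 0 fell (1 rose within the list; 2 rose and 1 fell at an unadjusted p below 0.05; camera adjusted p = 0.769, and 0.917 with an estimated correlation). The dopaminergic median of 0.04 (0.09 with the block, −0.12 and 0.28 within runs) was −0.16 with median scaling, −0.01 without undifferentiated replicate 1 and −0.25 without replicate 9. Of 16 glia genes 3 rose, 1 fell and 12 did not pass (3 and 2 within the list; camera adjusted p = 0.507, and 0.780 with an estimated correlation), Pmp22 at 2.83 ± 0.35. The glia median of 0.17 (0.22 with the block, 0.15 and 0.16 within runs) was −0.04 without undifferentiated replicate 9, and 1 rose without feeder replicate 10. Of 26 mesoderm and muscle genes 3 rose, 1 fell and 22 did not pass (3 and 1 within the list; camera adjusted p = 0.607, and 0.917 with an estimated correlation). Tcf15 was at −2.18 ± 0.24, and without feeder replicate 6 there were 0 rises and the median of 0.11 (0.14 with the block, 0.30 and −0.10 within runs) was −0.04. Endoderm genes rose in 3 of 27 cases, 2 fell and 22 did not pass (3 and 2 within the list; camera adjusted p = 0.651, and 0.917 with an estimated correlation). The epithelial adhesion gene Epcam was at −3.73 ± 0.55. The endoderm median of 0.10 (0.09 with the block, 0.11 and 0.03 within runs) differed in sign from the mean of −0.06 and was −0.08 with median scaling. In the blood and endothelium list 1 of 27 rose, Runx1 (1.79 ± 0.30), and 0 fell (1 within the list; 1 rose and 0 fell at an unadjusted p below 0.05; camera adjusted p = 0.408, and 0.917 with an estimated correlation). Its median was 0.31, 0.37 with the block, and 0.19 and 0.50 within runs. Of 36 stress and immediate early genes 2 rose, 2 fell and 32 did not pass (1 and 2 within the list; camera adjusted p = 0.651, and 0.934 with an estimated correlation), Ddit3 at 1.90 ± 0.29 and Pdk1 at −2.26 ± 0.27. The stress median of −0.20 (−0.18 with the block, −0.21 and −0.22 within runs) was 0.26 with values as deposited, and the test direction was up without undifferentiated replicate 5 (0.697). With values as deposited the test direction of the neural progenitor (0.954), dopaminergic (0.794), mesoderm and muscle (0.794), endoderm (0.543) and blood and endothelium (0.954) lists was down.

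Feeder and undifferentiated cells differed in 1820 probe sets (20.4%), 898 higher and 922 lower in feeder cells, or 722 and 720 genes, and groups did not overlap in 61.7% against 20% by chance. With the run as a block 1476 passed, and the differences within runs 1 and 2 correlated at 0.848 across all probe sets. With values as deposited (median of all probe sets 0.32 log2) 83.7% of calls were higher in feeder cells against 49.3%. The count was 1057 and 967 without undifferentiated replicates 1 and 9, and 463 and 548 without feeder replicates 6 and 10. It was 3326 with only the arrays of these groups. Calls held in every leave-one-out fit for 31 of 52 named genes.

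The fifth comparison set 4+11 day cells against the feeder fibroblasts. Among the largest falls below feeder cells was that of the fibril-associated Mfap5, at 13.7 ± 2.60 (SD, n = 3) against 468.9 ± 95.6 (n = 2), a log2 difference of −4.45 ± 0.26 (SE, adjusted p = 7.65e-05), and Ltbp2, Ptx3, C1qtnf3 and Thbs2 were at −4.61, −4.53, −4.46 and −4.35. Xist was at 6.41 ± 4.03 (n = 3) against 180.3 ± 10.3 (n = 2), a log2 difference of −3.75 ± 0.41 (adjusted p = 0.00142). Among the largest rises were Myl2 (4.59 ± 0.73, adjusted p = 0.00936) and Myh7 (4.01 ± 0.69, adjusted p = 0.0138). The Myl2 call was lost without feeder replicate 6 or 10 (adjusted p up to 0.111) and the Myh7 call also without 4+11 day replicate 4 (up to 0.188). Nes was at 460.3 ± 120.4 (n = 3) and 461.8 ± 156.8 (n = 2), a log2 difference of 0.01 ± 0.35 (adjusted p = 0.996) that ran from −0.34 to 0.35 as arrays were left out and was −0.07 with values as deposited.

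Of 48 fibroblast and matrix genes 14 fell, 0 rose and 34 did not pass (28 fell and 1 rose within the list; camera adjusted p = 4.97e-22, adjusted p = 0.206 with an estimated correlation). The median was −1.51, −1.50 with the block, and −1.16 and −1.70 within runs, and 8 and 6 fell without feeder replicates 6 and 10. Of 22 Hox genes 6 fell, 0 rose and 16 did not pass (10 fell within the list; 11 fell and 0 rose at an unadjusted p below 0.05; camera adjusted p = 1.24e-09, and 0.0374 with an estimated correlation), Hoxa7 at −2.56 ± 0.20 (adjusted p = 0.000289). Their median was −0.63, −0.80 with the block, and −0.62 and −0.85 within runs, and the falls numbered 3 without 4+11 day replicate 4, and 1 and 0 without feeder replicates 6 and 10. Mesoderm and muscle genes rose in 4 of 26 cases, 0 fell and 22 did not pass (7 and 1 within the list; camera adjusted p = 0.000829, adjusted p = 0.516 with an estimated correlation). Their median was 0.45, 0.22 with the block, and 0.27 and 0.21 within runs. The rises numbered 2 with the block, 0 without either feeder array, and 1 and 9 without 4+11 day replicates 4 and 8. Endoderm genes rose in 3 of 27 cases, 0 fell and 24 did not pass (6 rose within the list; camera adjusted p = 0.00348, adjusted p = 0.474 with an estimated correlation). The genes that rose were the epithelial keratins Krt8 (3.67 ± 0.71) and Krt18 (3.49 ± 0.76) and Foxa1 (3.02 ± 0.58). Without 4+11 day replicate 4 or either feeder array 0 rose, and the adjusted p reached 0.271, 0.337 and 0.289; the Foxa1 call was also lost without 4+11 day replicate 8, and that of Krt8 with the block (3.08, adjusted p = 0.0545). There were 5 rises without 4+11 day replicate 8, and the median was 0.63, 0.33 with the block, and 0.82 and −0.13 within runs.

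In the blood and endothelium list 2 of 27 rose, 0 fell and 25 did not pass (2 and 1 within the list; camera adjusted p = 0.0301, adjusted p = 0.772 with an estimated correlation): Cdh5 (2.22 ± 0.32, adjusted p = 0.00526; 0.0942 without feeder replicate 10) and Lmo2 (1.84 ± 0.31, adjusted p up to 0.161 without 4+11 day replicate 4 or either feeder array, and log2 1.72 with adjusted p = 0.0516 with the block). The list's adjusted p was 0.101 with the block, 0.0965 and 0.115 without 4+11 day replicates 4 and 12 and 0.0547 without feeder replicate 6, with 5 rises without 4+11 day replicate 8. Its median was 0.98, 0.70 with the block, and 0.84 and 0.09 within runs. For the neuron list 0 of 35 members passed (0 within the list; 5 rose and 2 fell at an unadjusted p below 0.05), while the list lay above other genes (camera adjusted p = 0.0376, adjusted p = 0.812 with an estimated correlation). The neuron median was 0.58, 0.81 with the block (camera adjusted p = 0.000142), and 0.28 and 1.53 within runs. The list's call was lost without 4+11 day replicate 8 (0.886), feeder replicate 6 (0.0504) or 10 (0.0807) or 4+8 day replicate 1 (0.0529) or 2 (0.0890), and without all 4+8 day arrays (0.179). For the neural progenitor list 0 of 31 passed (0 within the list; 4 rose and 1 fell at an unadjusted p below 0.05; camera adjusted p = 0.0522, and 0.812 with an estimated correlation). Its median was 0.37, 0.73 with the block (camera adjusted p = 0.000264), and 0.15 and 1.39 within runs, and the list passed without 4+11 day replicate 4 (0.0271) or 12 (0.000303), 4+8 day replicate 2 (0.0385) or 3 (0.0370) or feeder replicate 6 (0.0334).

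Few pluripotency genes differed by this test: 1 of 33 fell, Il6st (−2.33 ± 0.33; adjusted p up to 0.0898 without feeder replicate 6 or 10), and 0 rose (1 and 1 within the list; 4 fell and 3 rose at an unadjusted p below 0.05; camera adjusted p = 0.635, and 0.891 with an estimated correlation). Their median was 0.06, 0.10 with the block, and 0.03 and 0.20 within runs. Of 16 glia genes 2 rose, 1 fell and 13 did not pass (3 and 2 within the list; camera adjusted p = 0.867, and 0.934 with an estimated correlation). The glia median of 0.03 (0.13 with the block, −0.13 and 0.14 within runs) was −0.07 with values as deposited, −0.13 without 4+11 day replicate 8, where the test direction was down (0.886), and −0.02 without feeder replicate 10. In the dopaminergic list 0 of 15 passed (0 within the list; 2 fell and 0 rose at an unadjusted p below 0.05; camera adjusted p = 0.465, and 0.746 with an estimated correlation), and the median was −0.12, −0.10 with the block, and 0.10 and −0.03 within runs. In the cell cycle list 0 of 44 passed (0 within the list; 1 fell and 0 rose at an unadjusted p below 0.05; camera adjusted p = 0.300, and 0.917 with an estimated correlation). The cell cycle median of −0.14 was 0.08 with the block, 0.05 and 0.12 within runs, 0.06 without feeder replicate 10 and 0.08 without 4+11 day replicate 12. In these last fits the test direction was up (0.670 and 0.583), and the list passed without 4+11 day replicate 8 (0.000544) or feeder replicate 6 (0.00803). Of 22 imprinted genes 0 passed (0 within the list; 6 rose and 1 fell at an unadjusted p below 0.05; camera adjusted p = 0.0957, and 0.735 with an estimated correlation), with a median of 0.23, 0.26 with the block, and 0.57 and 0.37 within runs. The imprinted list passed with the block (0.0271), with values as deposited (0.0281) and without 4+11 day replicate 8 (0.0499) or 12 (0.0406) or feeder replicate 6 (0.00678). Of 36 stress and immediate early genes 2 fell, the amino acid response genes Trib3 (−2.33 ± 0.39) and Asns (−1.39 ± 0.30), and 0 rose (3 fell within the list; 5 fell and 0 rose at an unadjusted p below 0.05; camera adjusted p = 0.116, and 0.812 with an estimated correlation). Both calls were lost without feeder replicate 6 or 10 (adjusted p up to 0.169 for Trib3) and that of Asns also without 4+11 day replicate 8 or 12 (up to 0.290) and with values as deposited (0.0745). With the block Trib3 was at −2.36 (adjusted p = 0.0598) and Asns at −1.11 (0.0943), and both calls were lost. The stress median was −0.20, −0.32 with the block, and −0.15 and −0.56 within runs, and 0.03 without 4+11 day replicate 8. The list passed with the block (0.0271) and without 4+11 day replicate 4 (0.0482) or 12 (0.0329) or feeder replicate 6 (0.0439).

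Only 262 probe sets (2.93%) passed between 4+11 day and feeder cells, 101 higher and 161 lower, or 84 and 124 genes, and groups did not overlap in 39.5% against 20% by chance. With the run as a block 157 passed, 126 of them shared, and the differences within runs 1 and 2 correlated at 0.596 across all probe sets. The count was 133 without 4+11 day replicate 4, and 68 and 31 without feeder replicates 6 and 10. The values as deposited gave 25.2% of calls higher against 38.5%. The calls of Myl2, Myh7, Krt8, Krt18, Lmo2, Trib3 and Asns were lost without the other wash protocol (adjusted p from 0.0597 to 0.0917), and those of Myh7, Krt8, Krt18, Foxa1, Cdh5 and Asns with only the arrays of these groups (0.0515 to 0.140). Calls held in every leave-one-out fit for 7 of 28 named genes: Xist, Thbs2, Mfap5, C1qtnf3, Ptx3, Ltbp2 and Hoxa7.

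**Figure D4:**
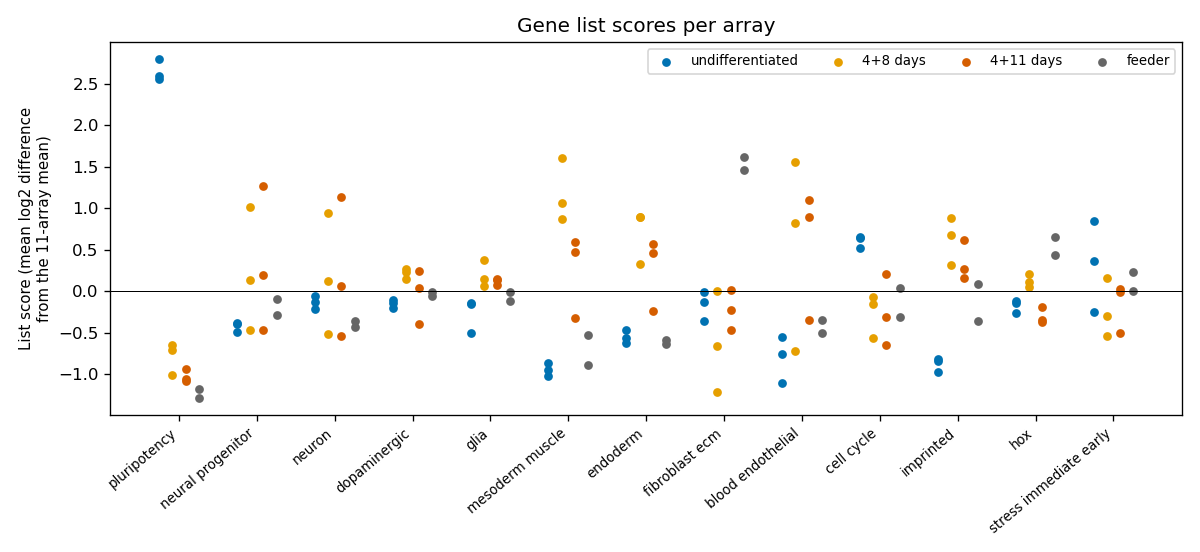
Each point is the score of 1 array for 1 gene list, the mean log2 difference of its members from the mean over the 11 arrays, coloured by group. In the neural progenitor list 4+11 day replicates 4, 8 and 12 scored 0.19, 1.26 and −0.47, and 4+8 day replicates 1, 2 and 3 scored 0.13, 1.01 and −0.46.

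Changes against undifferentiated cells overlapped. Between the differentiation times 1136 probe sets were called in the same direction, 460 higher and 676 lower, and 17 in opposite directions. Independent lists of these lengths would share 141.8 and 167.9. The log2 differences correlated at 0.680 against 0.499 in 100 simulations, with covariance 0.62 against 0.08 (difference 0.55). These drew unchanged groups with shared controls and 1 spread, so their shared calls (at most 1) were bound to be few. Real spreads differed, so their values are rough. Between 4+11 day and feeder cells 994 were shared, 424 higher and 570 lower, with 23 opposite, against 82.8 and 87.0 for independent lists. Correlation was 0.696 against a simulated 0.449, with covariance 0.55 against 0.08 (difference 0.47). The 3 undifferentiated arrays cannot be split 2 and 2, so part of the excess over independent lists may come from the shared controls. Without undifferentiated replicates 1, 5 and 9 the first overlap was 628, 734 and 582 and the second 502, 597 and 444.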

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

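Only the share of other probe sets that moved the same way and the share among the brightest 10% were written down beforehand. The other tests here, the Fisher test included, were chosen only after the result was seen.

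The transcripts added to every hybridisation as controls (BioB, BioC, BioDn and Cre, 9 probe sets), which no comparison uses, had a geometric mean signal 20.6 times higher on the 4+8 day arrays than on the other 8 arrays. The ratio was 9.61 after each array was divided by its median, and the lowest 4+8 day array (4974) lay above the highest other array (369.4). These transcripts do not come from cells.

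The 4+8 day group stood apart from all 3 other groups in 1038 probe sets, 519 higher and 519 lower, against 712 for undifferentiated cells. Where such a gene had other probe sets, 67.0% of 182 (122, confidence interval 59.7 to 73.8) moved the same way, against 117 of 136 for undifferentiated cells (two-sided Fisher exact p = 0.000124) and, untested, 28 of 31 for feeder cells, so effects of the scan session or chip lot on single probe sets could account for part of them and cannot be told from culture stage. Compression of bright signals on the other arrays does not account for them, since 6.65% (69) lay among the brightest 10% of probe sets, fewer than their share of all. The added control transcripts, at 20.6 times, might differ through the amount added, the hybridisation or the scan. Hybridisation or scan might also act on whole genes. Culture stage stays open and untested, as session and group coincide.

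Mmp3 and 4 other fibroblast list genes fell from undifferentiated to 4+11 day cells, and RNA of the feeder cells in the undifferentiated samples could produce such falls. For Mmp3 the lowest undifferentiated array, less the 4+11 day mean, was 2.87 times the higher feeder array, and means were 1541 ± 821.2 (SD, n = 3) in undifferentiated, 287.1 in feeder (n = 2) and 12.5 in 4+11 day cells (n = 3), which leaves feeder RNA open, since feeder cells were not measured together with ES cells and could make more Mmp3 there. For Thbs2 (0.145), Bgn (0.309), Serpinf1 (0.197) and Cxcl1 (1.69) the median share was 0.253, with a share of 0.207 for Xist, and the question stayed undecided. Among 72 genes high in feeder cells the median share was 0.143 (quartiles 0.0313 to 0.295), 23 had a share below 0.05 and 4 above 1. Synthesis of these transcripts by ES cells was not tested.

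In 4+11 day replicate 8 the neural progenitor score was 1.26, against 0.19 and −0.47 in replicates 4 and 12, and the blood and endothelium score −0.35 against 0.89 and 1.10. RNA quality stays open, since the beta-actin 3' to 5' ratio of 1.55 lay between 1.49 and 1.84 but the Gapdh ratio of 0.937 lay below 1.03 and 1.07. So does the fluidics run: the second run differed from the first by 0.0518 in undifferentiated and −0.20 in feeder cells, and replicate 8 from replicates 4 and 12 by 1.40, but run 2 held 1 array per group, the undifferentiated one under another wash protocol. Undifferentiated cells left in the culture would raise the pluripotency genes together, and the median share over 28 of them was −0.0526% (−26.9 to 64.1, with Sox2 at 53.9%). Replicate 2 of 4+8 days, from the other scan session, had similar scores (1.01 against 0.13 and −0.46, and −0.73 against 0.81 and 1.55), and a difference in cell types between cultures, untested, might give both.

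The 6 arrays of a comparison split into 3 and 3 in 10 ways, the real one included, too few for a share under 0.05. For 4+8 days against undifferentiated the real split gave 3316 calls and the highest other 0, for 4+11 days 1668 and 0, and between the differentiation times 2062 and 150, so 1 split of 10, the real one, reached the count in each.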

How the results depend on the processing

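The fits without the 4+8 day arrays and without the 2 arrays of the other wash protocol, and the list tests without each array, were chosen only after the results were seen; the other alternatives were set beforehand. No paired analysis was possible because no 2 groups share at least 2 replicate numbers.

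For the named genes there were 293 values, 226 of them called, and 4519 values under alternatives. Of these 3949 kept direction and side of the threshold, 462 were weaker, 23 were stronger and 85 reversed, with 0 reversals among called genes. The filter at the 60th percentile left all 240 values alike, and the trended and robust prior 291 of 293. Counts stayed within 1.5 times under median scaling, both pseudocounts, both filters and the trended prior.

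These counts moved, and the cause was not tested unless stated. Values as deposited gave 6052 for 4+8 days against undifferentiated and 3733 between the differentiation times. A threshold of 1 on the log2 change, which can only remove calls, gave 2160, 1091 for 4+11 days against undifferentiated and 1282 between the times. Only the arrays of the compared groups gave 535 between the times and 3326 for feeder against undifferentiated. The times had most spread, so 2062 may be too many. The fluidics run as a block gave 899 for 4+11 days against undifferentiated and 157 for 4+11 days against feeder. Without the 4+8 day arrays, which spread most, these were 2782 and 726, and 2947 for feeder against undifferentiated. Without the arrays of the other wash protocol, which leaves fewer arrays, the 5 counts were 2068, 395, 916, 778 and 123. Of 26 list calls, 4 were left with an estimated correlation (pluripotency against undifferentiated cells in all 3 comparisons, and Hox for 4+11 days against feeder), which widens the test by construction.

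Leave-one-out counts ran from 2257 to 3744 for 4+8 days against undifferentiated, 775 to 1567 for 4+11 days, 969 to 2426 between the times, 463 to 1225 for feeder against undifferentiated and 31 to 257 for 4+11 days against feeder. List calls ran from 25 to 32, and the overlaps from 582 to 734 (both times) and 444 to 597 (4+11 days and feeder). The moved values among these ran from 775 to 1078, from 969 to 1325, from 463 to 1057, from 31 to 133, from 582 to 734 and from 444 to 597. A single feeder array was assumed to vary like the other groups.

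All reversals were of genes without a call, and the cause was not tested. For 4+8 days against undifferentiated, values as deposited gave Cdk1 0.63, Gfap 1.06, Pax6 0.84, Mki67 0.42, Nr4a2 0.49 and Gata4 0.36. Median scaling gave Tubb3 −0.0932, Gfap 0.27 and Pax6 0.0307, and the fit without the other wash protocol Cdk1 0.0145. For 4+11 days against undifferentiated, Gata4 was 0.30 as deposited and 0.00223 without the other wash protocol, and Pax6 −0.0236 with median scaling and −0.0550 with the 5th percentile pseudocount. Between the times, values as deposited gave Gata4 −0.0542, Pax6 −0.53, Sox1 −0.68 and Tubb3 −0.34, and median scaling Pax6 −0.0542, Sox1 −0.13 and Col3a1 0.11 (0.10 without the other wash protocol). For feeder against undifferentiated, Tubb3 was 0.31 and Cdk1 0.11 as deposited, Sox1 −0.0278 with median scaling and Gfap −0.23 without the other wash protocol. For 4+11 days against feeder, Fgf4 was −0.0274 and Nes −0.0684 as deposited, Nr4a2 0.21 and Mki67 0.0642 with the block, and Mki67 0.0612 without the other wash protocol.

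Leave-one-out ranges that crossed 0 for 4+8 days against undifferentiated were Sox1 −0.0265 to 1.03, Tubb3 −0.00528 to 0.77, Cdk1 −0.17 to 0.0389, Gfap −0.56 to 0.35 and Pax6 −0.69 to 0.44. For 4+11 days against undifferentiated they were Tubb3 −0.0917 to 0.59, Th −0.17 to 0.39, Mki67 −0.12 to 0.33, Pax6 −0.57 to 0.60, Gata4 −0.15 to 0.0191 and Gfap −0.65 to 0.19. Between the times they were Sox2 −0.55 to 1.49, Pax6 −0.41 to 0.87, Sox1 −0.18 to 0.88, Tubb3 −0.45 to 0.33, Col3a1 −0.30 to 0.24, Col1a1 −0.71 to 0.37, Gfap −0.51 to 0.25 and Nr4a2 −0.52 to 0.13. Feeder against undifferentiated gave Th −0.0552 to 0.60, Mki67 −0.17 to 0.70, Gfap −0.23 to 0.42 and Sox1 −0.15 to 0.46. In 4+11 days against feeder they were Afp −0.23 to 0.83, Pou5f1 −0.11 to 0.24, Nanog −0.19 to 0.29, Fgf4 −0.11 to 0.18, Nes −0.34 to 0.35, Th −0.41 to 0.17, Nr4a2 −0.36 to 0.21, Mki67 −0.61 to 0.26 and Cdk1 −0.61 to 0.050.

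Background limits the dim genes, as log2(intensity + 8) compresses changes below it, and the number of arrays limits precision.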

Other observations

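The genes of this part were chosen only after their values were seen.

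Cells at 4+11 days differed from each of the other 3 groups in 12 probe sets, 8 higher and 4 lower. Cdh2, the neural cadherin, had a mean intensity of 1089 ± 135.8 (SD, n = 3) at 4+11 days, against 92.0 ± 7.80 (n = 3) in undifferentiated cells, 231.0 ± 62.3 (n = 3) at 4+8 days and 298.1 ± 15.4 (n = 2) in feeder cells. Its log2 differences were 3.45 (adjusted p = 1.67e-05), 2.22 (0.000572) and 1.83 (0.00322) in limma. Cd200, a membrane glycoprotein of neurons and immune cells, was at 151.0 ± 31.7 against at most 49.7 ± 12.9 elsewhere. The forkhead factor Foxq1 and the peroxisomal transporter Abcd2 were at 39.1 and 44.7 (n = 3), against at most 7.95 and 10.2 elsewhere. Tfpi2, a protease inhibitor, and Igfbp6, which binds insulin-like growth factor 2, were lower, at 4.09 ± 0.327 and 26.0 ± 12.8.

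Feeder cells differed from all other groups in 140 probe sets, 101 higher and 39 lower, and undifferentiated cells in 712, 476 higher and 236 lower.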
